A study of Mus musculus with 2 samples.

How the data were processed

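Chromatin accessibility was measured by DNase-seq, in which nuclei are treated with DNase I and the cut ends are sequenced, so that DNA not packed into nucleosomes gives many cuts. The 2 libraries came from kidney tissue of the mouse strain B6CASTF1/J, male and aged 8 to 10 months, and are labelled biological replicates 1 and 2. They form 1 group (n = 2), so no groups of animals were compared. The labels give the libraries separate biosamples and the same donor identifier. The p-values below are therefore across genes or motif matches inside a library, and the spread between the replicates may be partly technical.

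For each library the authors deposited 2 peak lists with a signal value per peak, a list of footprints (short stretches inside open sites that are protected from cutting), and a track of the FDR, a p-value adjusted for multiple testing, along the genome. Peaks and footprints were called separately in each library, as the deposited files hold 1 set per library. The labels and file names give the mouse build mm10. The aligner, the peak caller, the footprint caller and the scaling of the signal are not given in the sources used here. The thresholds of the 2 peak lists are not stated either. From the values, 100% of the peaks in the longer list of each library held a base with an FDR of 0.05 or less, and 100% of those in the shorter list a base with an FDR of 0.001 or less. The track held no value above 0.05 (highest 0.0499412 and 0.0499953), and the longer list was not checked at 0.001. These shares therefore do not settle the thresholds. The longer list was used as the main one, a choice made after seeing the files, and the shorter one as an alternative. The deposited footprints all carry the same score of 0.01, so they could not be ranked.

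The deposited signal values were whole multiples of 1 step per library, 0.0104 in replicate 1 and 0.00594 in replicate 2. This held for 100% of 125797 and 145585 peaks with a signal under 10, within 0.02 of a step. One step was taken as 1 cut or read. If both libraries were scaled to the same total, the ratio of the steps puts the depth of replicate 2 at 1.75 times that of replicate 1. The scale of the signal is not stated, so no absolute depth is given. A median peak held 91 and 124 steps. Counting error between replicates was computed from these numbers, and intervals cover counting error only. Shares have Wilson 95% intervals.

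Coordinates were compared with the GRCm38.p6 sequence and the GENCODE M21 annotation, the same build as mm10; every peak ended within its chromosome. Promoters were the 1000 bp on each side of a transcription start site (TSS) of a protein-coding transcript, for 21853 protein-coding genes. Exons, introns and the space between genes were also defined by protein-coding genes only. A site between protein-coding genes may therefore lie in a non-coding gene. The promoter signal of a gene was the highest signal of any peak overlapping this window. Distal peaks were those whose midpoint lay over 1000 bp from every protein-coding TSS and within 50000 bp of the gene's 5′ end. Peaks counted as shared when they overlapped by at least 1 bp, and overlaps were set against 100 random placements. For signal ratios, peaks were paired when each was the other's largest overlap.

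Before the data were examined, 22 gene lists (renal and other cell types in kidney, regulators, processes, housekeeping genes and other tissues) and 26 consensus motifs were fixed. All but 1 of the listed genes, Ahsp, had a match in the annotation. Each list's share of promoters with a peak was tested against all other protein-coding genes with Fisher's exact test (two-sided), and its median number of distal peaks with a permutation test (two-sided) against 10000 random lists of the same size. Both were adjusted over the 22 lists by the Benjamini-Hochberg method. A list was called only where both replicates passed an adjusted p of 0.05 in the same direction. For motifs, the share of matches inside peaks with their centre in a footprint was compared with that of the reversed, not complemented, consensus by Fisher's exact test (two-sided), with the same rule. The SP/KLF motif was left out because its reversed consensus is the motif itself, leaving 25. A control at positions shifted by 30 bp inside the same peak was added after seeing the data. The cutting preference of DNase I for certain sequences was not corrected here, and the effect of CAST/EiJ alleles on alignment to the reference was not analysed here.

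The genes named are the 3 members of each list with the highest mean promoter signal and the first members with no peak in either replicate (at most 2), the 10 genes with the most distal peaks found in both replicates, the 10 strongest shared peaks, and the list members with a promoter peak in 1 replicate only (count, with the 5 of highest signal). Some genes that met this rule are not reported here. Motifs were named by the 5 highest and 5 lowest ratios. Any other gene named was chosen after its values were seen. Alternatives covered the overlap needed for sharing, the peak list, the upper part of each list by signal, promoter and distal windows, matched background genes, all annotated genes, footprint position, region, signal scaling and leaving out each replicate.

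The tests were checked on simulated data. For promoter lists (20 runs over 21853 genes, with planted shares of 97% and 20% against the real share), 25 of 60 lists planted higher and 49 of 60 planted lower were called, with 1 call among 320 unplanted lists. Small lists can therefore miss a call upward, since most promoters have a peak already. For distal lists with 8 added peaks per gene, 51 of 60 planted lists were called, with 1 call among 380 others. This check used fewer random lists than the real test and permuted the counts over genes. It therefore did not keep the sharing of distal peaks between neighbouring members of a list. For motifs, 60 of 60 planted higher and 60 of 60 planted lower were called, with 0 calls among 380 others. Unplanted motifs and their reversed sequences were simulated with the same share. The 0 calls therefore do not cover a reversed sequence that differs by itself, for example in cutting preference. Effects were planted only in the larger lists and in motifs with many matches of both the motif and its reversed sequence. Recovery was therefore not checked for small lists, such as distal convoluted tubule (10 genes). Nor was it checked for motifs with few reversed matches, such as HNF1 (19). For overlaps, 70.1% of 129291 peaks were found where 70.0% were planted. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.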

Results

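Accessible chromatin was mapped in adult male kidney tissue of the mouse strain B6CASTF1/J in 2 libraries. Replicate 1 had 129291 peaks covering 25.5 Mb and replicate 2 had 148924 peaks covering 29.6 Mb, with a median width of 200 bp in each. Footprints numbered 289537 in replicate 1 and 415869 in replicate 2, and 89.3% and 86.1% of them overlapped the library's own peaks. At least 1 footprint lay in 74.8% (95% interval 74.6 to 75.1) of the peaks of replicate 1 and 82.9% (82.7 to 83.1) of those of replicate 2. Replicate 2 had more peaks and more footprints. By the steps of the signal values it was 1.75 times as deep as replicate 1, if both libraries were scaled to the same total.

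The comparison of the replicates asks how far a site seen in 1 kidney library was seen in the other. Strong sites were found in both, and weak ones often in 1 only. Of the peaks of replicate 1, 85.8% (95% interval 85.6 to 86.0) overlapped a peak of replicate 2. In the other direction, 74.5% (74.3 to 74.7) of the peaks of replicate 2 overlapped a peak of replicate 1. The mean of the 2 directions of this overlap was 80.1%. Its SD of 7.99 is not a spread between independent replicates. Random placement gave 2.36% and 2.05%. Among the top 10% of peaks by signal, 99.8% and 99.7% were shared, and among the bottom 10%, 43.1% and 29.2%. Each library had peaks of its own, 18369 in replicate 1 and 37977 in replicate 2, with median signals of 0.374 and 0.368 against 1.13 and 1.03 for shared peaks. Across 109303 paired peaks, which are not independent replicates, the signal had a Spearman correlation of 0.961 and a Pearson correlation of 0.970 on the log2 scale. The median log2 ratio of replicate 2 to replicate 1 was -0.10, with an SD of 0.34 against a median counting SD of 0.18. The replicates differed beyond the 95% range of counting error at 29.7% of pairs, and by more than 2-fold from the median ratio at 1.05%.

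**Figure D1:**
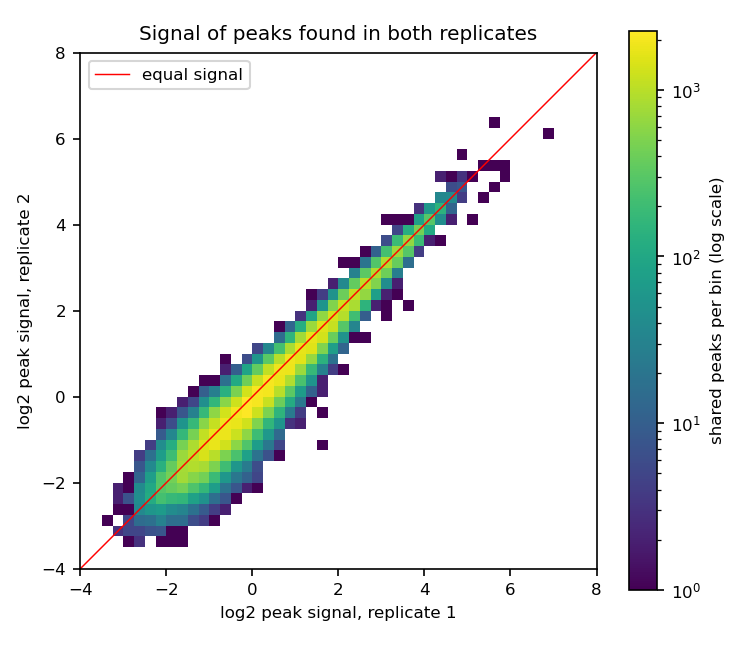
Log2 peak signal of the 109303 peaks paired between replicate 1 (x axis) and replicate 2 (y axis), in bins coloured by the number of peaks on a log scale; the red line marks equal signal. Bins follow the line, with a median log2 ratio of -0.10 and an SD of 0.34.

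The 10 strongest shared peaks mixed promoters with sites far from protein-coding genes. The highest signal was on chromosome 17 from 39846781 to 39846920, between protein-coding genes, with non-coding genes not considered. It lay 103670 bp from the 5′ end of the nearest protein-coding gene, Esp38, with 118 in replicate 1 and 74.3 in replicate 2 (mean 96.3 ± 31.1, SD, n = 2). The next was in the promoter of Dynlt1b, a dynein light chain gene, on chromosome 17 from 6429981 to 6430180 (53.4 and 83.6). A peak on chromosome 1 from 88277541 to 88277760 in the promoter of Trpm8, the cold-sensing channel, reached 38.6 and 40.8, and one in the promoter of Dnpep, an aminopeptidase, reached 34.7 and 33.8. Only the nearest protein-coding gene was looked up for the 10 peaks, so promoters of other genes may share them. The peak nearest Srl, on chromosome 16, lay 154 bp from the gene's 5′ end (31.6 and 52.3). Of the other 5 peaks, that nearest Limd1 lay in an exon (63.9 and 43.2) and that nearest Kpna1 in an intron (47.4 and 29.5). Those nearest Igf2bp3 (60.2 and 37.3), Gm8797 (49.2 and 39.8) and Gm15319 (30.1 and 35.3) lay between protein-coding genes. At 7 of these 10 peaks at least 50% of the 31-base words of the sequence occurred elsewhere on the chromosomes, a limit on what their signal counts. The highest peak, that nearest Esp38, was among them, with 82.7% of its words elsewhere. It therefore cannot be read as a single distal site. Only the assembled chromosomes and the mitochondrial genome were searched, so copies outside them were not counted.

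Accessible sites were concentrated at gene starts. Promoters held 21.1% ± 0.735 (SD, n = 2) of the peaks, 8.64 ± 0.302 times their share of the genome, and promoter peaks had the highest median signal, 1.70 ± 0.297. Introns held 36.1% ± 0.428 of the peaks and the space between protein-coding genes 37.8% ± 0.0511, with median signals of 0.781 and 0.699. Exons outside promoters held 5.03% ± 0.257. A promoter peak was present at 66.8% of 21853 protein-coding genes in replicate 1 and 68.5% in replicate 2. Both replicates had one at 14400 genes, replicate 1 alone at 201 and replicate 2 alone at 579.

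Base by base, the sequence with an FDR of 0.05 or less covered 46.3 ± 4.78 Mb (SD, n = 2), 1.75% of the sequenced genome. It fell to 37.5 ± 3.78 Mb at 0.01 and 29.9 ± 3.21 Mb at 0.001. At 0.05, 88.3% of this sequence in replicate 1 was also under the threshold in replicate 2, and 76.3% the other way round. The libraries' own peaks held 58.8% and 58.7% of it.

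The gene lists ask which cell types and processes of the kidney had open promoters. Proximal tubule genes, which serve reabsorption of filtered solutes, had a promoter peak at 20 of 22 members in both replicates (90.9%), a higher share than other genes (adjusted p = 0.0457 and 0.0434, Fisher's exact test, two-sided). Their highest promoter signals were at Pck1, a gluconeogenic enzyme, with 8.09 ± 0.744 (SD, n = 2), Miox, which breaks down inositol, with 7.92 ± 0.165, and Lrp2, the endocytic receptor megalin, with 7.18 ± 1.04. Slc22a8, an organic anion transporter, and Slc7a13, an amino acid transporter, had no promoter peak in either replicate. Transcription factors of the renal epithelium had one at 16 of 16 (adjusted p = 0.0128 and 0.0175, Fisher's exact test), led by Ppara, a regulator of fatty acid oxidation (11.8 ± 1.22), Maf (9.97 ± 1.07) and Tfcp2l1 (7.82 ± 0.170). Endothelial genes were likewise higher, at 12 of 12 (exact adjusted p = 0.0320 and 0.0434), led by Ehd3 (6.11 ± 0.663), Egfl7 (2.59 ± 0.530) and the VEGF receptor Flt1 (2.50 ± 0.0377).

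The other renal lists were not called. Loop of Henle genes had a peak at 11 of 12 members in replicate 1 and 12 of 12 in replicate 2 (adjusted p = 0.165 and 0.0434, Fisher's exact test), with Egf at 6.59 ± 0.0346 and Umod, which encodes uromodulin, at 3.51 ± 0.462. Distal convoluted tubule genes had one at 10 of 10 in both (exact adjusted p = 0.0676 and 0.0579), with the kinase gene Wnk1 at 11.1 ± 0.402, Emx1 at 4.88 ± 0.418 and Sgms2 at 3.12 ± 0.0497. Principal cell genes had one at 10 and 9 of 10 (exact adjusted p = 0.0676 and 0.242), with Tfcp2l1 again, the sodium channel subunit Scnn1g at 6.97 ± 0.274 and Gata3 at 4.13 ± 0.212. Intercalated cell genes had one at 9 of 10 in both (exact adjusted p = 0.234 and 0.242). The proton pump subunit Atp6v0a4 reached 6.76 ± 1.46, Rhbg 3.05 ± 0.451 and Slc4a9 2.39 ± 0.208, and the anion exchanger Slc4a1 had no promoter peak. Podocyte genes had one at 10 of 12 in both (exact adjusted p = 0.394 and 0.442). Cdkn1c was at 4.15 ± 0.457 and Synpo at 2.91 ± 0.402, and Nphs1, which encodes nephrin, had none. All 8 androgen-responsive renal genes had one (exact adjusted p = 0.0996 and 0.0927), with Odc1, an enzyme of polyamine synthesis, at 10.9 ± 0.342, Cyp4b1 at 5.83 ± 0.0718 and Cyp2j13 at 1.79 ± 0.0332. Stromal and mural genes had one at 9 of 11 in both (exact adjusted p = 0.394 and 0.602). Col1a1 (7.34 ± 0.130), Tagln (3.51 ± 0.289) and Cspg4 (3.49 ± 0.131, a peak also in the promoter of Odf3l1) led, and the renin gene Ren1 had none. Tubular injury genes had one at 10 and 9 of 12 (exact adjusted p = 0.394 and 0.776), with Krt8 at 3.11 ± 0.241, Spp1 at 1.98 ± 0.0583 and Vim at 1.5 ± 0.0261, and none at Lcn2 or Timp1. Embryonic nephron progenitor genes had one at 4 and 5 of 8 (exact adjusted p = 0.475 and 0.776), with Sall1 at 4.45 ± 0.435, Osr1 at 1.48 ± 0.338 and Cited1 at 0.854 ± 0.334, and none at Six2 or Gdnf.

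**Figure D2:**
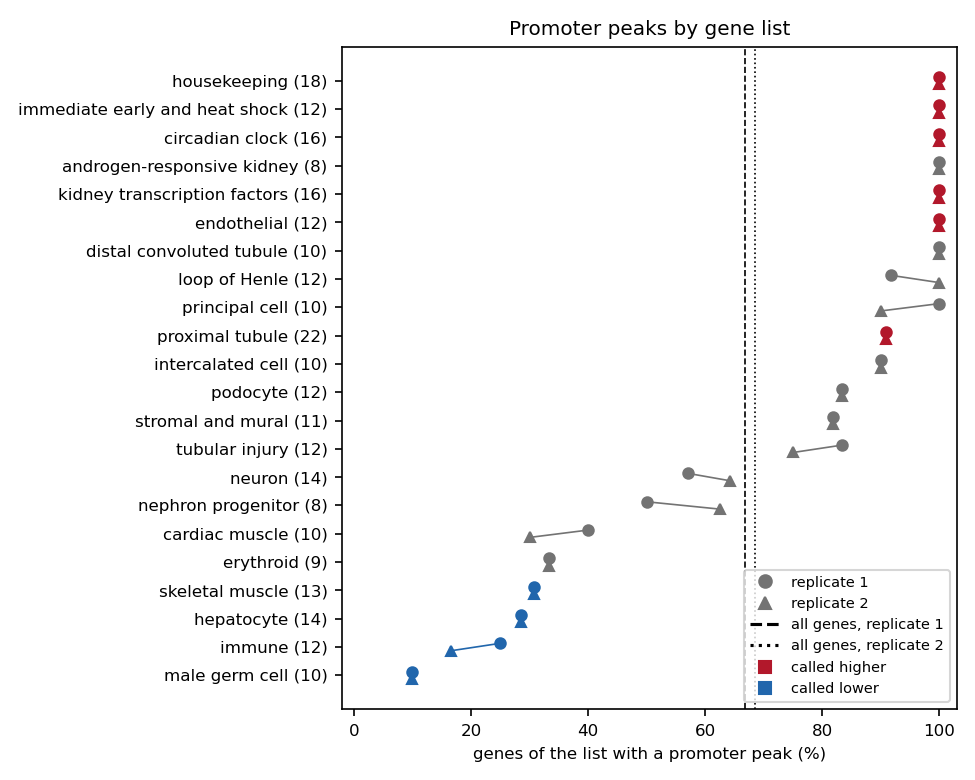
Share of each gene list's members with a promoter peak (x axis, %), in replicate 1 (circles) and replicate 2 (triangles), with list sizes in brackets; vertical lines mark all protein-coding genes, 66.8% and 68.5%. Red lists (6) were called higher and blue lists (4) lower in both replicates.

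Clock, early response and housekeeping genes had the highest median promoter signals of the 22 lists. Circadian clock genes had a promoter peak at 16 of 16 members (adjusted p = 0.0128 and 0.0175, Fisher's exact test, two-sided), with a median promoter signal of 12.7 in replicate 1 and 13.4 in replicate 2. Nr1d1, a repressor of the clock loop, reached 24.1 ± 3.14 (SD, n = 2), Per1 21.3 ± 0.230 and Nr1d2 20.5 ± 1.24. Immediate early and heat shock genes had one at 12 of 12 (exact adjusted p = 0.0320 and 0.0434), with Jun at 23.6 ± 0.504, Klf6 at 16.8 ± 0.572 and Dusp1 at 12.1 ± 0.0851. Housekeeping genes had one at 18 of 18 (exact adjusted p = 0.0128 and 0.0115), with the ribosomal gene Rplp0 at 24.6 ± 2.24, Actb at 17.0 ± 0.927 and Eef2 at 16.5 ± 0.0171. The median signals of these lists lay at or above the percentile 99.8 of random lists of the same size in both replicates. Those of proximal tubule genes lay at 58.8 and 58.0, and those of endothelial genes at 41.6 and 37.5. The labels give no time of day.

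Male germ cell, immune, hepatocyte and skeletal muscle genes had fewer open promoters than other genes. Male germ cell genes had a promoter peak at 1 of 10 members in both replicates (adjusted p = 0.00751 and 0.00350, Fisher's exact test, two-sided), Sycp3 at 1.37 ± 0.101 (SD, n = 2), and none at the protamine genes Prm1 and Prm2. Immune genes had one at 3 and 2 of 12 (exact adjusted p = 0.0142 and 0.00350), with Cd74, the invariant chain of antigen presentation, at 1.75 ± 0.464 and Cd68 at 0.745 ± 0.0782. C1qa had one in replicate 1 only, and Ptprc and Csf1r had none. Hepatocyte genes had one at 4 of 14 (exact adjusted p = 0.0142 and 0.0136) and none at Alb or Apoa1. Their highest were Apoh at 5.89 ± 0.399, a peak also in the promoter of Prkca, Cyp2e1 at 4.34 ± 0.830 and Fga at 2.16 ± 0.547. Skeletal muscle genes had one at 4 of 13 (exact adjusted p = 0.0337 and 0.0180) and none at Ckm or Myh4. Actn3 (9.20 ± 0.803) and Mylpf (7.82 ± 1.19) shared their peaks with the promoters of Zdhhc24 and Tbc1d10b, and Casq1 reached 2.15 ± 0.161.

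The remaining lists, cardiac muscle and neuronal genes of other tissues among them, were not called. Erythroid genes had a promoter peak at 3 of 9 members (adjusted p = 0.107 and 0.0541, Fisher's exact test), among them Tal1 at 1.46 ± 0.0965 and Epor at 1.23 ± 0.103, and none at the globin genes Hba-a1 and Hbb-bt. Cardiac muscle genes had one at 4 and 3 of 10 (exact adjusted p = 0.136 and 0.0385), with Ryr2 at 3.46 ± 0.392, Tnni3 at 1.07 ± 0.0113 and Myl2 at 0.679 ± 0.00997, and none at Myh6 or Nppa. Neuronal genes had one at 8 and 9 of 14 (exact adjusted p = 0.571 and 0.776), with Rbfox3 at 3.55 ± 0.0823, Snap25 at 2.40 ± 0.325 and Syp at 2.40 ± 0.494, and none at Slc32a1 or Neurod1. Only 11 list members had a promoter peak in a single replicate, 6 in replicate 1 and 5 in replicate 2. They came from 9 lists, 2 each from the podocyte and the stromal and mural lists and 1 each from the other 7. The 5 of highest signal were Des (0.488 in replicate 1), Tbr1 (0.446 in replicate 2), Nkx2-5 (0.416 in replicate 1), Avpr2 (0.405 in replicate 1) and C1qa (0.395 in replicate 1).

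The calls of gene lists depended on the test, the promoter window and the background. With a permutation test (two-sided) against random genes not matched on any property, the calls of clock, housekeeping and renal transcription factor genes held (adjusted p up to 0.0209, 0.0117 and 0.0209), as did those of immune, hepatocyte, skeletal muscle and male germ cell genes (0.0330, 0.0330, 0.0421 and 0.00880). Those of proximal tubule, endothelial and early response genes ended (0.0554, 0.0510 and 0.0510). With the same test against random genes matched on promoter CpG content, the calls of clock, housekeeping and renal transcription factor genes ended (permutation adjusted p up to 0.543, 0.179 and 0.050), as did those of immune, hepatocyte and skeletal muscle genes (0.868, 0.512 and 0.481), and early response genes did not pass (0.256). Loop of Henle, distal convoluted tubule, intercalated cell and androgen-responsive genes were then called higher (adjusted p up to 0.0215, 0.0465, 0.0154 and 0.00880), and proximal tubule, endothelial and male germ cell genes passed (0.00880, 0.0123 and 0.0167). All members of the clock, housekeeping, renal transcription factor and early response lists had a promoter peak. Matched random lists can equal that share but not exceed it. Endothelial, distal convoluted tubule and androgen-responsive genes also had a peak at all members and passed, so a full share did not by itself prevent passing. For the lists that failed, matched random lists reached the full share too often for a call. Their shares were therefore not told apart from those of genes with similar CpG content. Whether CpG content is the cause was not tested. In the shorter peak list proximal tubule, endothelial and skeletal muscle genes no longer passed (adjusted p up to 0.0622, 0.0860 and 0.0607, Fisher's exact test). With a promoter window of 2 kb the calls of endothelial, early response, hepatocyte and skeletal muscle genes ended (exact adjusted p up to 0.0639, 0.0639, 0.0735 and 0.125). In the upper part of the peak lists by signal those of endothelial and hepatocyte genes ended (0.0647 and 0.0567), and cardiac muscle genes were called lower (0.0440). Without peaks near another gene's TSS those of housekeeping and immune genes ended (0.0508 and 0.0628), and loop of Henle, distal convoluted tubule and androgen-responsive genes were called higher (exact adjusted p up to 0.0291, 0.0164 and 0.0251).

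Distal sites gathered around proximal tubule, renal regulator, clock, early response and housekeeping genes. Proximal tubule genes had a median of 13.2 ± 2.47 (SD, n = 2) distal peaks within 50 kb, renal transcription factors 11.8 ± 2.47, clock genes 15.8 ± 3.89, immediate early and heat shock genes 15.5 ± 0.707 and housekeeping genes 11 ± 0.707. All protein-coding genes had a median of 5 in replicate 1 and 6 in replicate 2. These 5 lists were called higher (adjusted p up to 0.00147, 0.00880, 0.00147, 0.00330 and 0.0194, permutation test, two-sided), and 0 lists were called lower. Endothelial genes had 10.2 ± 2.47 and passed in replicate 2 only (permutation adjusted p = 0.263 and 0.0403). The other renal lists, podocyte (6.75 ± 1.77), loop of Henle (7.25 ± 1.77), distal convoluted tubule (5 ± 0.707), principal cell (7.25 ± 0.354), intercalated cell (8.50 ± 1.41) and androgen-responsive (6.25 ± 0.354), did not pass. Neither did stromal and mural (8.00 ± 0), immune (6.25 ± 1.06), erythroid (6.5 ± 0.707), nephron progenitor (3.25 ± 0.354), tubular injury (5.25 ± 0.354), hepatocyte (6.25 ± 0.354), neuronal (4.00 ± 0.707), skeletal muscle (5.50 ± 0.707), cardiac muscle (8.25 ± 1.06) or male germ cell genes (5.50 ± 1.41). With a window of 20 kb the calls of renal transcription factors and housekeeping genes ended (adjusted p up to 0.0669 and 0.443), and that of housekeeping genes also with 100 kb (0.315).

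The densest neighbourhoods lay on chromosomes 2, 5, 11, 15 and 19. Pim3, a kinase gene, had 38 distal peaks found in both replicates within 50 kb of its 5′ end, and its neighbours Alg12 and Creld2 on chromosome 15 had 35 each and share a promoter peak of 20.5 ± 0.870 (SD, n = 2). Trim8 had 33, Pxn, which encodes paxillin, 31, Hoxb5 30 and Sirt4, a mitochondrial sirtuin, 29. Tmem189, Cebpb, a transcription factor gene of gluconeogenesis and inflammation, and Kdm6b, a histone demethylase gene, had 28 each. Replicate 2 had 63 distal peaks around Hoxb5 and replicate 1 had 41.

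Footprints ask which transcription factor sequences were protected from cutting. Matches of the motif of HNF4, a regulator of proximal tubule and liver genes, had their centre in a footprint at 33.9% ± 3.87 (SD, n = 2), against 6.62% ± 1.31 for the reversed motif, a ratio of 5.16 ± 0.438, the highest against this control. The next ratios were 4.84 ± 0.399 for the insulator protein CTCF (80.2% ± 5.84 of matches), 4.00 ± 0.291 for CRE (72.8% ± 2.01), 3.86 ± 0.831 for the PPAR/RXR repeat (49.6% ± 3.94) and 2.73 ± 0.382 for the E-box CACGTG (40.6% ± 2.35). Of 25 motifs, 14 were higher than their control in both replicates (adjusted p up to 0.0385, Fisher's exact test, two-sided), 1 was lower and 10 were not called. The lower one was the forkhead motif, at 4.41% ± 0.247 against 8.11% ± 0.896 (ratio 0.546 ± 0.0298, adjusted p up to 9.76e-06), a call that ended when any overlap with a footprint counted (ratio 0.804, adjusted p up to 0.108, Fisher's exact test). The other lowest ratios, none called, were MEF2 at 0.773 ± 0.293, grainyhead at 0.852 ± 0.189, ESRR at 0.951 ± 0.102 and GATA at 1.03 ± 0.132. RFX, NFI and REST had no ratio because a control share was 0 in at least 1 replicate.

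The order of the motifs depended on the control. Against positions shifted by 30 bp the ratio of HNF4 was 2.67 ± 0.284 (SD, n = 2), while CTCF rose to 21.9 ± 7.04 and PPAR/RXR to 8.04 ± 2.27. NFI at 20.5 ± 2.68 and REST at 18.3 ± 3.32 were next to CTCF, CRE was at 4.24 ± 0.438 and the E-box at 2.57 ± 0.211. The HNF1 motif, of a renal epithelial regulator, was in a footprint at 34.4% ± 1.57 of matches and was not called against the reversed motif (ratio 1.47 ± 0.164), which had 19 matches per replicate. Against the shifted positions its ratio was 4.40 ± 1.10 (adjusted p up to 9.59e-12, Fisher's exact test). With the shifted control 15 motifs were higher and 6 lower, and 10 of the 14 higher calls were kept. The lower ones were AP-1 (ratio 0.832) and PU.1/IRF (0.562), both higher against the reversed motif, OCT (0.470), GATA (0.456) and MEF2 (0.376), not called against it, and forkhead (0.242). In distal peaks alone 9 motifs were higher, and the call of PPAR/RXR, whose reversed motif had 14 and 17 matches in all peaks with 2 in a footprint in each replicate, ended there (ratio 3.03, adjusted p up to 0.120, Fisher's exact test). The calls of NRF1, RFX, NFI and PU.1/IRF ended there too.

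**Figure D3:**
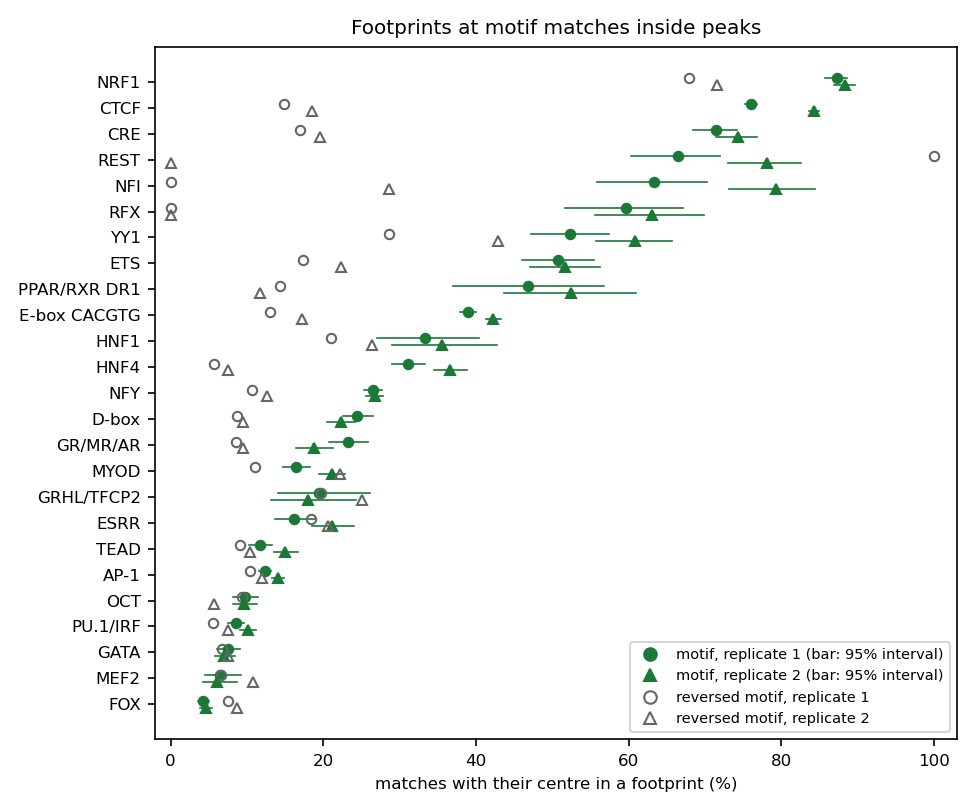
Share of matches inside peaks with their centre in a footprint (x axis, %) for 25 motifs, filled symbols, and for their reversed sequence, open symbols, in replicate 1 (circles) and replicate 2 (triangles); bars are 95% Wilson intervals. Reversed motifs with few matches, such as REST with 1, give unstable shares.

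Footprints were shared less often than peaks at an overlap of at least 1 bp. They were also narrower, with median widths of 10 and 11 bp against 200 bp, so the shares are not directly comparable. Random placement was along the chromosome for peaks and inside a peak for footprints. Of the footprints of replicate 1, 67.7% (95% interval 67.6 to 67.9) overlapped a footprint of replicate 2, and 44.5% (44.4 to 44.7) the other way round. The mean of the 2 directions was 56.1%, with an SD of 16.4 that is not a spread between independent replicates. Among footprints inside the library's own peaks, 67.7% and 46.3% were shared, and random placement of these inside the same peak gave 44.3% and 31.9%. Shared footprints were wider, with medians of 13 and 18 bp, against 8 and 9 bp for the others. A wider footprint overlaps another more easily, so this difference may follow from the overlap rule, which was not tested.

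The X chromosome is present once in male animals, and no correction for copy number was made. It had 21.6 ± 2.0 peaks per Mb (SD, n = 2) against 56.6 ± 5.64 on autosomes, a ratio of 0.382 ± 0.00351. The median signal of its peaks was 0.574 ± 0.00329 of the autosomal one, and that of its promoter peaks 0.530 ± 0.0400. The Y chromosome had 47 peaks in replicate 1 and 111 in replicate 2, so its values rest on few sites. Among peaks in the upper part of each list by signal, the X ratio was 0.237.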

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

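The stronger part of the footprint lists, an alternative fixed at the start, was not run because the deposited score is constant. No paired analysis was possible because there is 1 group and no contrast. Control positions shifted by 30 bp, the exclusion of peaks near another gene's TSS, the permutation test of promoter lists without matching and the replicate ratios were chosen after seeing the data. Requiring a reciprocal overlap of 50% lowered the mean share of peaks found in both replicates to 70.6% and that of footprints to 39.5%. The upper part of each peak list by signal raised the share of peaks to 88.9%. Both shares need both libraries, so they could not be checked by leaving out a replicate. Their 2 directions gave 74.5% and 85.8% for peaks, and 44.5% and 67.7% for footprints. The Spearman correlation was 0.964 with reciprocal overlap and 0.949 in the upper part by signal. The share of peaks at promoters was 15.5% with 500 bp, 26.1% with 2 kb, 29.3% in the upper part by signal, 25.5% in the shorter list and 27.5% with all annotated genes (20.6% to 21.6% without each replicate). Lists with fewer open promoters fell from 4 to 2 with 2 kb and to 1 with CpG-matched background; lists with more went from 6 to 3 with a permutation test without matching and stayed between 4 and 8 otherwise, but with CpG matching only 2 of the 6 were kept. The call of endothelial genes ended in 4 alternatives, those of early response, hepatocyte and skeletal muscle genes in 3 each, those of proximal tubule, housekeeping and immune genes in 2 each, those of clock and renal transcription factor genes in 1 each and that of male germ cell genes in 0. Distal lists called higher fell from 5 to 3 with 20 kb. Motifs called higher fell from 14 to 9 in distal peaks alone. Motifs called lower went from 1 to 0 with any overlap and to 6 with shifted control positions, where AP-1 (0.832), PU.1/IRF (0.562) and OCT (0.470) changed direction and GATA (0.456) and MEF2 (0.376) were called. The X to autosome density ratio was 0.237 in the upper part by signal and 0.364 in the shorter list (0.380 to 0.385 without each replicate). The sequence under the FDR threshold was 37.5 Mb at 0.01 and 29.9 Mb at 0.001, and 42.9 to 49.7 Mb at 0.05 without each replicate; stricter thresholds cover less by construction. The cause of the other shifts was not tested.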

Other observations

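The tests of counting error, of proximal tubule content and of neighbouring promoters, and the replicate ratios themselves, were chosen after their values or parts of them had been seen, and the annotation around some of the strongest peaks had been looked at before the test of sequence copies was written. Over 22 lists and 3 kinds of peak (66 comparisons), the log2 signal ratio of replicate 2 to replicate 1 around list genes, relative to the median of all shared peaks, passed an adjusted p of 0.05 in 4. Androgen-responsive renal genes were lower in replicate 2 over all peaks within 50 kb (median -0.27 over 8 genes, adjusted p = 0.0132, permutation test, two-sided) and over distal peaks (-0.34, adjusted p = 0.0198), while their promoter peaks did not pass (0.05, adjusted p = 0.936). Proximal tubule genes were lower by less (median -0.09 over 22 genes, adjusted p = 0.0429), and promoter peaks of principal cell genes were higher (0.29 over 8 genes, adjusted p = 0.0429, permutation test). Of the 8 androgen-responsive genes, 7 were below 0, with the organic anion transporter gene Slco1a1 at -0.48, Kap at -0.38, Cyp4a12a at -0.37 and Cyp4b1 at -0.30, and Odc1 was at 0.29.

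For the androgen-responsive genes, the level of signal of their peaks is argued against as the whole cause, since among 10000 random lists matched on signal level the median of -0.27 had a permutation p of 0.0010. Fewer proximal tubule cells in replicate 2 would lower proximal tubule genes about as much, and among lists of 8 drawn from both lists, which have 2 genes in common, the permutation p was 0.0334, against this as the whole cause. That test assumes that the genes of both lists depend equally on these cells, and the value lies near the threshold. The median was also lower than in random lists at 20 kb (-0.32) and at 100 kb (-0.19). The labels give both libraries the same donor identifier, so whether 2 animals are compared is not known, and neither a biological explanation nor a difference in library preparation was tested.

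The 10 strongest shared peaks differed between replicates by a median of 0.52 on the log2 scale, against 0.12 for the peaks ranked 11 to 500. Counting error falls as signal rises, so it would not make the strongest peaks differ by more than the next ones, and it is argued against as the whole cause (permutation p = 0.00020 among sets of 10 of the 500 strongest, two-sided, the lowest that 10000 sets can give). Sequence in several copies may contribute: at 7 of the 10 peaks at least 50% of the 31-base words occurred elsewhere on the chromosomes, against 9 of the 490 peaks ranked next (Fisher's exact test, two-sided, p = 8.80e-10), and 0 of the 10 matched the mitochondrial genome. The peak nearest Srl, whose sequence was unique on the searched chromosomes, differed by 0.83, so copies found there do not cover every case. No biological explanation was tested.

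Of 61 genes fixed as markers of other tissues, 20 had a promoter peak in both replicates. A neighbouring gene's promoter is argued against for most, since 15% of the 20 (95% Wilson interval 5.24 to 36.0) had their strongest peak within 1 kb of another protein-coding TSS, against 17.5% of all genes with a promoter peak (Fisher's exact test, two-sided, p = 1). CpG-rich promoters may contribute: the median CpG observed/expected ratio was 0.427 in members with a peak and 0.255 in those without, a difference of 0.172 (permutation test, two-sided, p = 0.00614), although the bootstrap 95% interval of -0.0264 to 0.339 includes 0. Tnnt3 (0.083), Rbfox3 (0.104), Myl2 (0.139), Fga (0.182) and Cyp2e1 (0.190) had promoter peaks at the lowest ratios, which CpG content leaves open. Apoa2, Casq1 and Gad1 also had ratios below the median of members without a peak. The ratio was taken around the gene's 5′ end, while the peak may lie at another TSS of the gene. No biological explanation was tested.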
